A study of Drosophila melanogaster with 3 samples.

How the data were processed

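Kc167 cells were grown at 25 degrees, and cells were fixed with 1% formaldehyde for 10 min, per the labels' protocols. Chromatin was digested with 400 units of HindIII, the cut ends were filled in with biotin-labelled nucleotides and ligated, and biotinylated DNA was sequenced from both ends, per the labels' protocols. The deposited files held 1 line per read pair in 4 columns, the arm and base position of each read, with no strand and no header. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build, mapping filters and any removal of repeats are not given in the sources used here. The 14 names in the files comprised 6 chromosome arms and 8 scaffolds of heterochromatin or unplaced sequence, such as 2LHet, YHet, U and Uextra. The labels assign 2 runs to library 1 and 1 run to library 2, from separate preparations, and permutation p-values were computed over positions or random placements, and the binomial test over read pairs, none of them over libraries.

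Positions were read as given and counted from 1. Pairs with a position below 1 were left out (14 and 29 in the runs of library 1, 166 in library 2). Pairs with identical positions at both ends were counted once within each library, after the runs of library 1 had been pooled. The same molecule could be listed 1 base apart in another run. Counting pairs within the same 16 base steps at both ends once was therefore added as an alternative, after seeing the data. Different molecules that fall in the same steps are merged too, so this alternative does not isolate repeats. In library 2 it kept 7878208 of 8184423 pairs between chromosomes, but 5135037 of 15028070 same-arm pairs under 1 kb. No annotation of the build in the files was used: of 17673 genes on the arms in a table of Release 6, 1484 end beyond the highest position seen on their arm, so that the builds differ. The planned comparisons of borders, domain lengths, gene lists and eigenvectors with gene positions were therefore not run, and regions are named by coordinates alone, in the build of the files.

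Same-arm maps were made in 10 kb bins and merged to 20, 50 or 100 kb where stated. Maps were balanced by iterative correction with up to 50 rounds, leaving out the diagonal, the next bin, and bins under 10% of the median coverage. Between-library correlations used log10 of observed over expected pairs with a pseudocount of 0.5, over bin pairs with at least 10 pairs in all, after thinning to the shallowest run. Bin pairs of 100 kb with at least 20 pairs were tested by a two-sided binomial test with the expected share set per separation. The decay exponent is the least squares slope of log10 contact frequency on log10 separation in 20 steps per decade. The insulation score is the log2 of mean balanced contact in a 100 kb square beside each bin over the arm mean, and borders are its minima with a prominence of at least 0.1. Contact between arms was set against the product of the arms' totals, and contact between ends against the 100 kb bin totals of each pair of arms. Long-range contacts are 20 kb bin pairs 1 Mb or more apart, at least 3 times the expected value with at least 10 pairs in each library, and highest among their 5 by 5 neighbours. The named regions follow a rule set before the data were examined: the 10 borders of largest prominence, the 5 longest domains and the 5 long-range contacts with the largest lower value of both libraries. Settings and tests other than those said to be added were fixed at that time too, with some exceptions. Cut sites at borders, contact inside domains, the correlation of the insulation score and the recurrence of molecules between runs were not planned. Neither were the neighbours of long-range contacts and the eigenvector sign at centromere ends.

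HindIII sites were inferred from the reads because no genome sequence was used. Peaks of far pair ends, smoothed over 201 bases, were taken as sites where at least 600 ends, summed over both libraries, lay within 300 bases. The limit of 600 was set after seeing the distribution of ends per peak, in the gap between weak and strong peaks, and 400 and 800 were considered as well. This gave 30072 sites, and 85.0% of far ends in library 1 and 85.2% in library 2 lay within 300 bases of one, in 14.4% of the positions. Intervals for the ratio of sites or of pair ends between parts of an arm came from a bootstrap over 1 Mb windows.

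The procedures were tested on simulated data at the depth of the real maps. All of 180 planted borders on a map like 2L were found within 1 bin, and none was reported on a map without domains. The planted borders lay 100 kb or more apart, while the reported domains had a median length of 80 kb. All planted borders had the same contrast of contact. The reported borders varied in prominence, from the limit of 0.1 upward with a median of 0.51. Recovery of closer or weaker borders was therefore not simulated. The test of differing bin pairs was first simulated with 200 bin pairs raised in the same map: 79% were called at 2-fold with 8 unchanged ones, and all at 4-fold with 80 unchanged ones, among 128792 tested. The simulation was then changed, after this result was seen, to raise 100 in each map, which gave 81.5% with 5 unchanged ones at 2-fold and all with 13 unchanged ones at 4-fold. The shares called cover the raised bin pairs as a set. They were not broken down by depth, so the share called among bin pairs with few read pairs is not known. Unchanged bin pairs made up 4.82% of the calls at 2-fold and 28.6% at 4-fold in 1 direction, and 2.98% and 6.10% in both directions, so that strong changes in 1 direction lead to many false calls. A planted exponent of -1.3 was recovered as -1.30, and planted blocks correlated with the eigenvector at 0.999. These blocks took either sign at random, while the real eigenvectors had the same sign in most bins. A pattern of that kind was not simulated. Of 60 planted long-range contacts 91.7% were found. They were planted above the limit of 3 times, on a map without coverage bias, and closer than the 2620 kb median of the reported ones. Recovery of weaker or more distant contacts was not simulated. Unrelated border sets gave p below 0.05 in 6.5% of 200 trials, in the circular shift test. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9. Intervals are 95% Wilson intervals. Alternatives covered repeat counting, bin size, square size, prominence, balancing, separation range, end length, thresholds and each library alone.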

Results

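Chromosome contacts were mapped by Hi-C in Kc167 cells, a line derived from fruit fly embryos, after digestion of crosslinked chromatin with HindIII. The data comprised 3 sequencing runs of 2 separately made libraries: library 1 was sequenced in 2 runs and library 2 in 1 run, so that every comparison between libraries rests on n = 2. There was 1 group of cells and no second condition, and the design addresses how closely repeated maps of the same cells match and how the genome is partitioned into contact domains. The runs of library 1 listed 34055596 and 46053582 read pairs and library 2 listed 92703188. Pairs with the same positions at both ends made up 16% and 17.7% of the listed pairs in the runs of library 1 and 45.4% in library 2. After such repeats were counted once, library 1 held 65214019 distinct pairs and library 2 held 50613554.

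Molecules recurred between the runs of library 1 but rarely between the libraries. Of 200000 pairs between arms drawn from run 1, 16.2% had a partner within 1 base at both ends in run 2, against 0.244% in library 2. With 1 end moved by 40 bases these shares fell to 0.004% and 0.008%. The runs of library 1 are therefore not independent samples of contacts, and they were summed.

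Most pairs on the 6 chromosome arms joined loci of the same arm (77.9% ± 0.82, SD, n = 2 libraries). Pairs between chromosomes made up 17.2% ± 0.63, and pairs between the arms of 1 chromosome 4.81% ± 0.19. The share between chromosomes was 15.3% (95% Wilson interval 15.3 to 15.3) in run 1 and 17.8% (17.8 to 17.8) in run 2 of library 1, and 17.7% (17.7 to 17.7) in library 2. These intervals cover counting error only. In this share the runs of library 1 differed by more than the libraries did, and the same held with all listed pairs. The order turned without same-arm pairs under 1 kb or under 20 kb, and in 16 base steps. In 16 base steps, pairs between chromosomes were 4042673 of 21333477 and 6114309 of 27887819 in the runs. They were 9534022 of 43122856 in library 1 and 7878208 of 30679728 in library 2. The libraries differed by more than the runs in same-arm pairs under 1 kb apart, which were 26.5% and 24% of the pairs in the runs, 25.2% in library 1 and 32.5% in library 2. In 16 base steps such pairs were 6215138 of 43122856 in library 1 and 5135037 of 30679728 in library 2. Their share was then lower, and the libraries lay closer together. Without same-arm pairs under 1 kb the share between chromosomes was 22.5% in library 1 and 26.2% in library 2, and without all those under 20 kb it was 29.5% and 32.5%.

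Contact maps of the libraries were closely alike. Across 176123 bin pairs of 20 kb, separated by up to 2 Mb, in maps thinned to the same total number of pairs but not matched at each separation, observed over expected contact correlated between libraries with Pearson r = 0.857 and Spearman rho = 0.838. The corresponding r was 0.889 between the runs of library 1 and 0.876 between random parts of library 1. Bin pairs are not independent replicates. The random parts were drawn from the pooled runs, so a molecule listed 1 base apart could enter both parts. The effect of such shared molecules on the runs or on the random parts was not tested, for r or for the differing bin pairs below. At 100 kb, 299 of 124087 bin pairs (0.241%) differed between libraries by a binomial test with Benjamini-Hochberg adjustment at 0.05, of which 165 were higher in library 1 and 134 in library 2. This test sets a single library against another and takes read pairs as independent, so that it covers counting error only. Between the runs 74 of 119268 differed, and between random parts of library 1 none of 120097 did, with 3.44% below 0.05 before adjustment. When the expected share also took account of each library's bin coverage, 74 bin pairs differed between libraries and 44 between runs. The share that differed between libraries was 0.568% with all listed pairs, 0.564% in 200 kb bins and 0.126% in 16 base steps.

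Contact frequency fell steeply with separation on every arm. Between 20 kb and 1 Mb the exponent averaged -1.26 ± 0.015 over the 5 major arms (SD, n = 2 libraries). It was -1.23 ± 0.017 on 2L, -1.29 ± 0.017 on 2R, -1.27 ± 0.015 on 3L, -1.28 ± 0.015 on 3R and -1.24 ± 0.011 on X, and -1.16 ± 0.0083 on the short chromosome 4. The X exponent exceeded the mean of the autosome arms by 0.0279 in library 1 and 0.0207 in library 2, which is more than the spread of that difference between libraries (SD 0.0051), although 2L and chromosome 4 were shallower than X. The mean difference, 0.0243, became 0.0453 from 100 kb to 5 Mb, 0.0434 on the balanced map and 0.0170 in 16 base steps. An exact permutation test of 2 against 2 values cannot give a p below 0.333, so no test was made. The exponent depended on the range of separations: it was -0.99 between 10 kb and 300 kb.

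**Figure D1:**
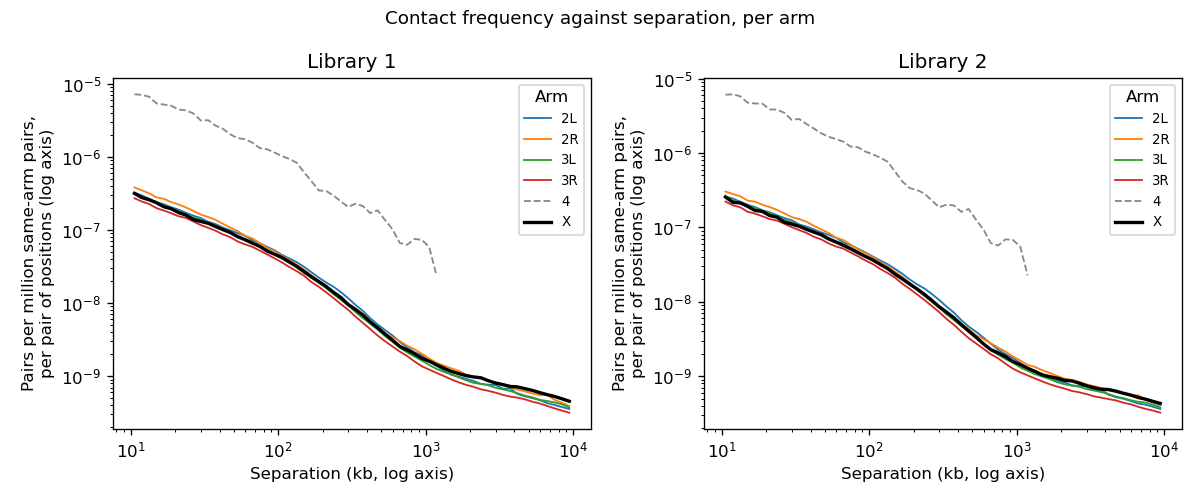
Contact frequency, as same-arm pairs per pair of positions scaled to each arm's own total (log axis), against separation in kb (log axis), 1 line per arm, library 1 on the left and library 2 on the right. Curves of the 5 major arms run close together in both libraries, and chromosome 4 lies higher, since its total is spread over the fewer pairs of positions of a short arm.

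Every arm was divided into contact domains at places that both libraries marked. At 10 kb resolution 1099 borders were called on the summed map with a border of each library within 1 bin. They comprised 186 on 2L, 207 on 2R, 223 on 3L, 258 on 3R, 13 on chromosome 4 and 212 on X. Density was 9.28 borders per Mb of scored sequence on the 4 autosome arms and 9.97 on X. It ran from 8.34 on 2L to 9.99 on 2R and 11.7 on chromosome 4, so that X was no denser than 2R in these borders. With the borders of each library alone, X was the densest of the major arms. X then had 11.52 borders per Mb against 11.25 on 2R in library 1, and 11.64 against 10.99 in library 2. The 1093 domains between neighbouring borders had a median length of 80 kb, with quartiles of 40 and 160 kb and a longest domain of 670 kb. Contact between bins of the same domain exceeded contact across 1 border at matched separation by 0.73 ± 0.013 on the log2 scale (SD, n = 2), with borders always taken from the other library. This is a mean over 9 separations, along which the value ran from 0.26 to 0.96 in library 1 and from 0.28 to 0.93 in library 2.

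Border positions matched between libraries far more often than by chance. Of the 1226 borders of library 1, 1101 (89.8%, 95% Wilson interval 88.0 to 91.4) had a border of library 2 within 1 bin. Circular shifts of the borders along each arm gave a mean of 29.4% and at most 44.5% (permutation p = 1e-05, one-sided, the smallest that 100000 shifts can give). The insulation score itself correlated between libraries with r from 0.986 on 3L to 0.995 on chromosome 4, across bins. Sharing ranged from 86.6% on X to 91.6% on 2L among the major arms. In a comparison that was not planned, border bins held 2.86 inferred HindIII sites against 2.52 per scored bin, a ratio of 1.13 (two-sided permutation p = 2e-05 over circular shifts, the smallest they can give). Border positions and the density of cut sites are therefore not independent. On the map that was not balanced for coverage, 1948 borders were called.

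The 10 borders of largest prominence, a measure of how deep the dip of the insulation score is on the log2 scale, lay on all 5 major arms. The deepest was at X 12650001 to 12660000, with a prominence of 3.53, followed by 2L 16250001 to 16260000 with 3.44 and 2L 10200001 to 10210000 with 3.27. Prominence was 3.25 at X 17800001 to 17810000, 3.24 at 3L 15490001 to 15500000, 3.18 at 3R 19170001 to 19180000 and 3.13 at 3R 5610001 to 5620000. The remaining borders were at 2R 12460001 to 12470000 with 3.07, X 9440001 to 9450000 with 3.05 and X 4560001 to 4570000 with 3.02. At the border of largest prominence the insulation score was -2.51 in library 1 and -2.13 in library 2. It was not the lowest score in library 2, where 2L 10200001 to 10210000 had -2.35. Of the 5 longest domains, 3 lay on X. They spanned X 11690001 to 12360000 (670 kb), X 21260001 to 21930000 (670 kb), 2L 22160001 to 22710000 (550 kb), X 14180001 to 14680000 (500 kb) and 2L 11490001 to 11980000 (490 kb). In the domain at the inner end of X 47.8% of the bins had too little coverage to be scored, against 5.97% to 9.09% in the others.

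Against the product of the arm totals, the arms of chromosome 3 met more often than expected and those of chromosome 2 did not, but this contrast depended on the expectation. Contact of 3L with 3R exceeded expectation by 0.15 ± 0.0047 on the log2 scale (SD, n = 2), the highest value of the 15 pairs of arms under this expectation, and contact of 2L with 2R was -0.012 ± 0.0012. An expectation fitted to the arm totals without the same-arm cells, chosen after seeing the data, gave 0.047 for chromosome 3, below the 0.084 of 2L with chromosome 4, and turned the direction for chromosome 2, to 0.033.

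Ends next to the centromere contacted each other strongly across arms. The innermost 2 Mb of 2L, 2R, 3L, 3R and X met at 0.62 on the log2 scale above expectation in the summed map, 0.72 in library 1 and 0.48 in library 2. The value depended on the length taken, with 1.104 for 1 Mb and 0.21 for 4 Mb. Random windows of 2 Mb gave a median of 0.0022 and at most 0.26 (permutation p = 1e-05, one-sided, the smallest that 100000 draws can give). The strongest pair was 2R with 3L, at 1.17 ± 0.21 (SD, n = 2), followed by 2L with 2R at 0.87 ± 0.20 and 2L with 3L at 0.86 ± 0.22. Pairs that included 3R had lower values, from 0.20 to 0.31. All 10 pairs were above 0 in both libraries, and every pair was higher in library 1. Whether reads at these ends are uniquely placed was not tested. Short pairs away from inferred sites lay at 0.425 and 0.481 of the autosome level (library 1 and library 2) in the first Mb of 2R. They lay at 0.341 and 0.401 at 3L 23000001 to 24000000, but at 0.921 and 0.917 in the first Mb of 3R. Telomere ends met at 0.16 (permutation p = 0.0002, one-sided). Centromere ends met telomere ends at -0.095 (permutation p = 1e-05, one-sided, in the lower tail, a tail not among the tests set beforehand). This p is not a test of avoidance. The value sums 2 placements per pair of arms, while each draw took 1 window per arm. Expected pairs come from the bin totals of the same pair of arms, so raised contact among centromere ends by itself lowers this value.

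**Figure D2:**
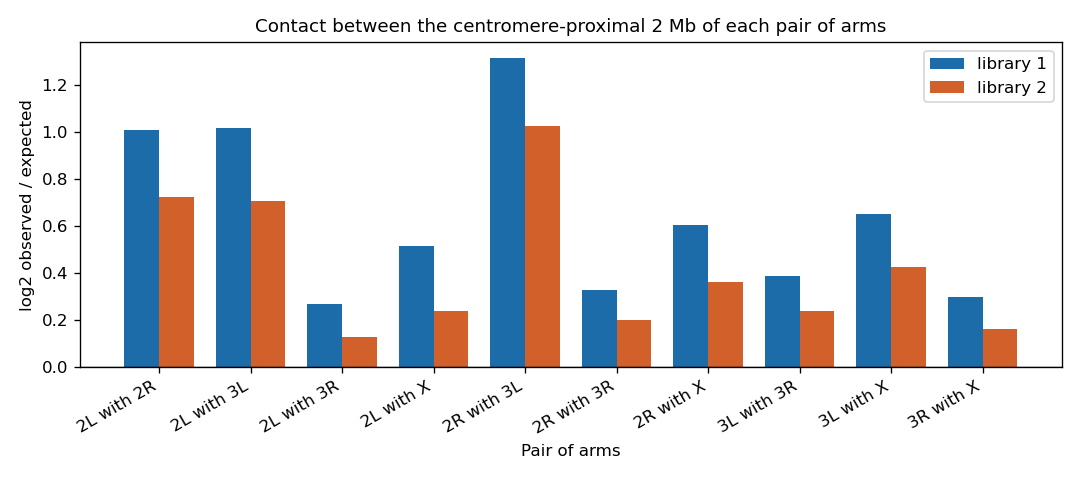
Contact between the innermost 2 Mb of each pair of arms as log2 observed over expected (y axis), with 1 bar per library. The 3 pairs among 2L, 2R and 3L reach 0.71 to 1.32 and the pairs with 3R 0.13 to 0.39.

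A few large blocks of raised contact stood out between arms, although they held few of the pairs. With a limit of 2 times the expected pairs in each library and at least 20 pairs in each, chosen after seeing the map, 525 groups of adjoining 100 kb bin pairs were found between arms, of which 455 were single bin pairs. Only 7 groups held 10 or more bin pairs, with 0.343% of the pairs between arms in library 1 and 0.305% in library 2. Of these, 4 joined the centromere ends of 2L, 2R and 3L, and 3 lay elsewhere. In the smallest of the 4, 2R 1400001 to 1600000 with 3L 23100001 to 24100000, a single cell of 1 kb by 1 kb held 15.1% and 16.1% of the pairs, against at most 2.23% in the other 6. The first of the 3 joined 2R 4000001 to 4800000 with X 10400001 to 10800000, at 5.37 times the expected pairs in library 1 and 4.80 times in library 2. Another joined 2R 17500001 to 18600000 with 3L 3400001 to 3700000, at 5.45 and 4.88 times. The last joined 2R 3700001 to 4800000 with X 13000001 to 13200000, at 4.46 and 4.52 times. Contact of both X segments with 2R was highest at 2R 4300001 to 4400000 in both libraries and lower on both sides.

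**Figure D3:**
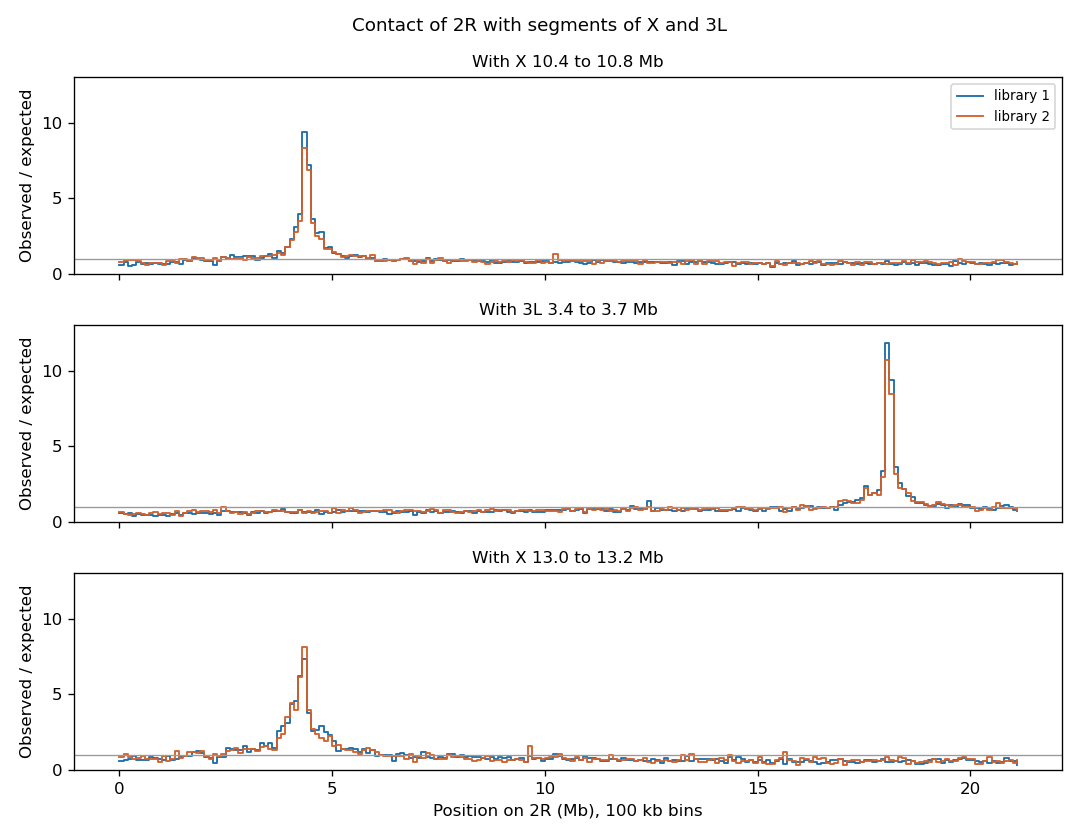
Observed over expected pairs (y axis) between 100 kb bins of 2R (x axis, Mb) and a segment of X, of 3L and of X, from top to bottom, with 1 line per library. Both X segments peak in the same 2R bin, at 9.38 and 8.31 times the expected pairs for the first segment and 7.36 and 8.15 for the second, and the 3L segment peaks at 2R 18000001 to 18100000 with 11.8 and 10.7.

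X carried fewer pair ends than the autosomes. The median number of ends per 100 kb bin on X was 0.723 of that on the autosome arms in library 1 and 0.758 in library 2 (mean 0.740 ± 0.025, SD, n = 2). Inferred HindIII sites were more widely spaced on X, 4608 bases on average against 3762 on 2L to 4020 on 3R. Per inferred site, a measure added after seeing the data, X had 0.831 ± 0.015 of the autosome level. Coverage per site was not even along the arms. On 2L it was 1.39 and 1.35 of the autosome level (library 1 and library 2) in the outermost Mb, 0.754 and 0.759 from 1000001 to 11000000, and 1.07 and 1.08 from 11000001 to 22000000. On X it was 0.697 and 0.701 from 1000001 to 8000000 and 0.901 and 0.935 from 8000001 to 21000000, where single windows of 1 Mb ranged from 0.690 to 1.08 in library 1. The Mb of 2R from 9000001 to 10000000 reached 1.26 and 1.25. The stretches were delimited after their values were seen.

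**Figure D4:**
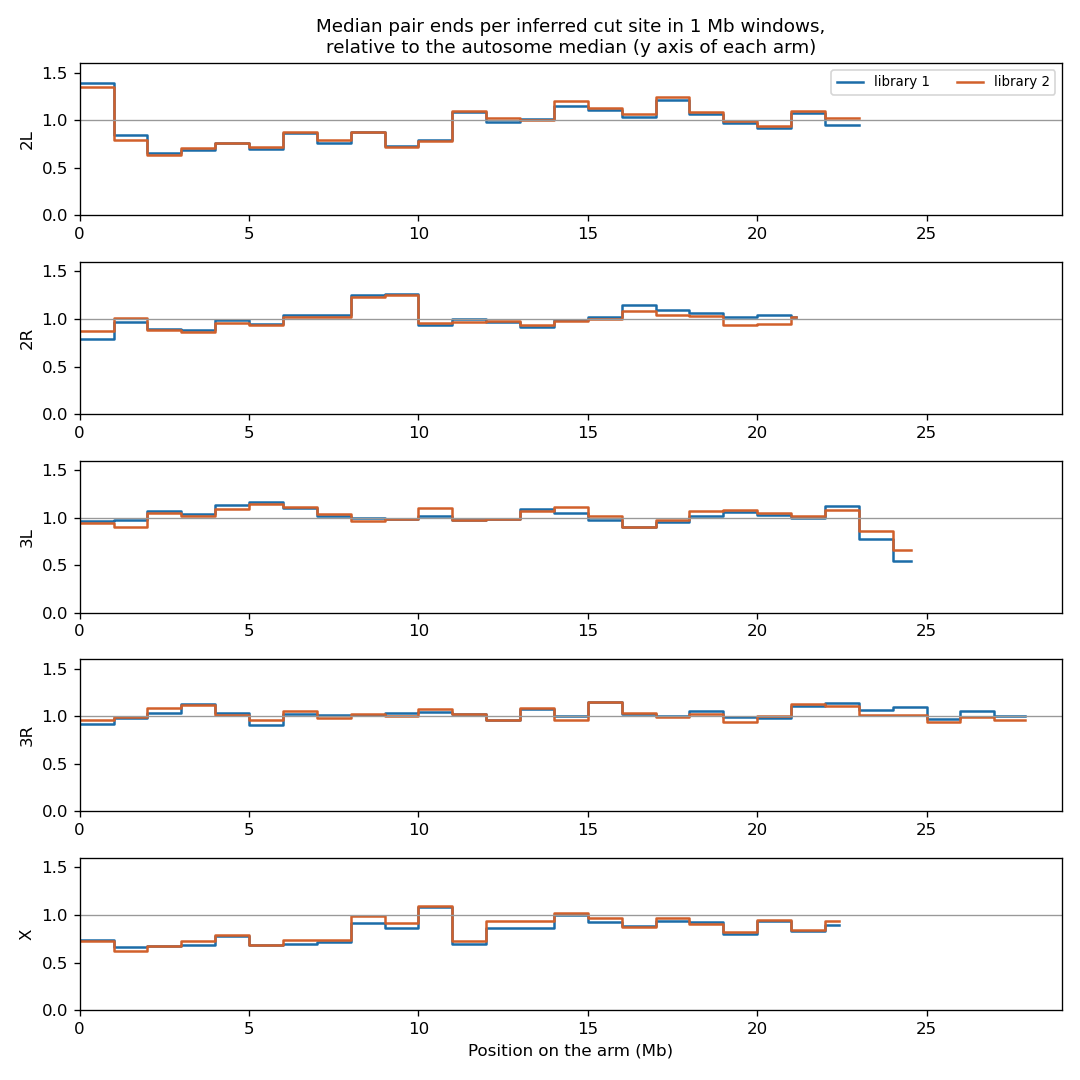
Median pair ends per inferred HindIII site in windows of 1 Mb relative to the autosome median (y axis) along each major arm (x axis, Mb), with 1 line per library. Both libraries step up at 11000001 on 2L and at 8000001 on X, and 3R stays between 0.908 and 1.15.

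Large-scale contact patterns along each arm recurred between libraries. The first eigenvector of the 100 kb correlation map correlated between libraries with Pearson r of 0.975 on 2L, 0.979 on 2R, 0.955 on 3L, 0.945 on 3R and 0.898 on X, across bins, with rho from 0.897 on X to 0.971 on 2L. Its share of the variance was 15.8% on X and 21% to 26.3% on the other arms in library 1. All but 5 to 17 bins per arm in library 1 and 7 to 17 in library 2 had the same sign. On 2R 15 of the 17 bins of the rarer sign in each library lay in the innermost 2 Mb, and on 3L 13 of 13 and 11 of 12, so that the sign sets the centromere end of these arms apart. On 2L, 3R and X at most 5 lay there.

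Strong contacts over 1 Mb or more were found on all 5 major arms. In 20 kb bins 618 contacts reached 3 times the expected value in both libraries, 155 on 2L, 113 on 2R, 134 on 3L, 114 on 3R and 102 on X, with a median separation of 2620 kb. The strongest joined 2L 17980001 to 18000000 with 2L 21600001 to 21620000, at 125 times the expected value in library 1 and 110 times in library 2. The next were X 8360001 to 8380000 with X 13280001 to 13300000 (108 and 128 times), 3R 12040001 to 12060000 with 3R 24360001 to 24380000 (97.6 and 213), X 10500001 to 10520000 with X 13160001 to 13180000 (90.8 and 102) and 2R 11760001 to 11780000 with 2R 18460001 to 18480000 (80.7 and 85.5). In 16 base steps the lower library of these 5 contacts had 72.5, 61.4, 43.1, 47.7 and 66.2 times, in the order given. Their sizes, and their order after the first, thus depended on whether pairs in the same 16 base steps were counted once. Such counting can merge different molecules as well as repeats. In 412 of the 618 the busiest cell of 1 kb by 1 kb held under 50% of the pairs in each library, and 251 of these also had neighbouring bin pairs at 2 times the expected value or more. In 320 of the 618 the neighbouring bin pairs lay below 2 times. Taken alone, library 1 gave 3343 such contacts and library 2 gave 1583, so that the count rests on requiring both. It also rests on balancing, since the map that was not balanced gave 3227 in both libraries.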

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

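Pairs with an end on a scaffold outside the 6 arms entered none of the comparisons, and they made up 8.14% of the distinct pairs in library 1 and 8.58% in library 2. The tests in this part were chosen after the values were seen. The heterochromatin scaffolds contacted the centromere ends of the arms, and mostly those of the arm they are named for. Relative to the innermost 2 Mb of each arm's contact with other chromosomes, XHet met the end of X at 4.35 ± 0.027 on the log2 scale (SD, n = 2), 2LHet the end of 2L at 3.52 ± 0.095, 3LHet the end of 3L at 2.87 ± 0.13 and 2RHet the end of 2R at 2.33 ± 0.18. Each of these 4 values was the highest among the 5 arm ends and chromosome 4. 3RHet departed from this: it met the end of 3R at 1.21 ± 0.063 and the ends of 3L at 1.71 ± 0.24 and 2R at 1.32 ± 0.23. In library 2 the ends of 3R and 2R were level, at 1.162 and 1.155.

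YHet took 0.0731% of the distinct pairs in library 1 and 0.173% in library 2. It met the end of 3L at 2.01 ± 0.15, of 2L at 1.68 ± 0.63 and of 2R at 1.48 ± 0.23. The ends of 3L and 2L were level in library 1, at 2.12 and 2.13. The unplaced scaffolds U and Uextra had their highest values with the end of 3L, 1.62 ± 0.081 and 1.59 ± 0.055. Whether reads on these scaffolds are uniquely placed was not tested, and misplaced reads are not excluded as the source of these pairs.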

How the results depend on the processing

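Of 85 alternatives to 13 results, 53 were classed as the same, 31 as moved and 1 as reversed. The class of the same did not require an unchanged value, and its bounds differed between results. It took in the centromere ends at 0.21 and 1.104 against 0.62, and 412 and 918 long-range contacts against 618. X coverage of 0.779 against 0.740 was classed as moved. Values moved with the counting of repeats, with bin size and balancing, and with the expectation used. The settings with 16 base steps, a fitted expectation, capped bin pairs, different chromosomes, inferred sites and the busiest cell were chosen after seeing the data. Borders shared between libraries ranged from 79.9% to 94.1% over 10 alternatives. The centromere ends stayed above 0 in all 6, but their value ran from 0.21 with 4 Mb ends to 1.104 with 1 Mb ends around the reported 0.62 (0.48 to 0.72 in 1 library). The one-sided permutation p was 1e-05 throughout, the smallest the draws can give, and so cannot rank these alternatives. The eigenvector correlation as the median over the 5 arms, 0.955 as reported, was 0.936 to 0.966 in 3 alternatives, while X alone was 0.898 as reported.

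The share between chromosomes was 14.4% with all listed pairs, 24.3% and 31.0% without same-arm pairs under 1 and 20 kb, and 23.9% in 16 base steps (16.8% to 17.7% in 1 library). The decay exponent was -1.28 with all listed pairs, -1.19 from 100 kb to 5 Mb, -0.99 from 10 to 300 kb, -1.32 on the balanced map and -1.16 in 16 base steps (-1.272 to -1.251 in 1 library). X exceeded the autosome arms by 0.0453 from 100 kb to 5 Mb, 0.0434 on the balanced map and 0.0170 in 16 base steps (0.0207 to 0.0279). Map correlation was 0.812 with all listed pairs, 0.932 in 100 kb bins, 0.927 on raw pairs and 0.955 with at least 40 pairs. Differing bin pairs were 0.568% with all listed pairs, 0.564% in 200 kb bins, 0.0596% with balanced shares and 0.126% in 16 base steps.

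Borders numbered 678 in 20 kb bins and 1948 on the raw map (1221 to 1226 in 1 library), and long-range contacts 3227 on the raw map (1583 to 3343 in 1 library). Contact of 2L with 2R was -0.060 without the outer and inner 2 Mb and turned to 0.033 with the fitted expectation (-0.013 to -0.011), and that of 3L with 3R was 0.16 and 0.047 (0.15 to 0.15). X coverage was 0.663 of the autosomes for same-arm pairs over 20 kb, 0.779 in 16 base steps and 0.831 per site (0.723 to 0.758). Except for the smaller number of larger bins, the cause was not tested. Alternatives for gene starts, domain length and gene lists were not run, since no annotation of the same build was used. Depth limits which bin pairs enter the 20 kb correlation. A minimum of 40 pairs also changes which separations are compared, so that the effect of depth on the correlation was not isolated.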

Other observations

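The tests of coverage along 2L and X, of the contact between the X segments and the copy number of 1 of them, of the named contacts of 2L and 2R and of repeat counting as the whole cause were chosen after the values were seen, and the eigenvector comparison was not planned. The number of domain borders per 100 kb bin varied with the first eigenvector of each arm. Across bins the absolute Spearman rho was 0.456 on 2L, 0.205 on 2R, 0.411 on 3L, 0.498 on 3R and 0.483 on X. Over all circular shifts the two-sided permutation p was 0.0094 on 2R and at most 0.0045 on the other arms, the smallest their bin numbers allow, and adjusted over the 5 arms it was at most 0.0094. The density of inferred HindIII sites showed absolute rho of at most 0.0805 with the eigenvector (smallest two-sided permutation p = 0.31).

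The 3 blocks of contact between 2R and segments of X and 3L peak at a place, with lower contact on both sides. Reads of repeated sequence set at the wrong locus are argued against in these 3. The busiest 1 kb by 1 kb cell held at most 0.536% of a block's pairs, where a pile-up was predicted to reach 10%. Such reads stay open for the centromere block of 2R 1400001 to 1600000 with 3L, where the busiest cell held 15.1% and 16.1%. The other centromere blocks were not part of this prediction, and it does not cover reads spread over many cells. If both X segments lie next to the same place of 2R, they should meet each other, and they did, at 9.05 times the expected value of the arm in library 1 and 8.79 times in library 2, against at most 1.45 among 186 other places of X; the named contact of X 10500001 to 10520000 with X 13160001 to 13180000 lies in these segments and had been seen before this test, and without its 100 kb bin pair the values were 7.86 and 7.59. An extra copy of X 10400001 to 10800000 fits its coverage per site, 1.35 times that of the inner part of X in the library with the lower ratio, while against the autosome level per site it had 1.22 and 1.29 (1.46 and 1.59 for short pairs), 3L 3400001 to 3700000 had 1.39 and 1.33 (1.29 and 1.51), and X 13000001 to 13200000 had 0.750 and 0.740. A rearrangement near 2R 4300001 to 4400000 in this line is a candidate explanation for the X blocks, and no biological explanation was tested between groups, since the design has 1 group of cells.

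Coverage per site stepped at 11000001 on 2L and 8000001 on X in both libraries. Coverage per site already divides out the density of cut sites, so that density was set against pair ends per Mb instead. Sites per Mb in the outer over the inner part had a 95% bootstrap interval from 0.861 on 2L and 0.892 on X. The intervals of pair ends lay below, narrowly on 2L, and reached at most 0.856 and 0.851. Since the stretches were delimited by their coverage per site, this restates the step, and no conclusion on its cause is drawn from it. Uneven digestion or ligation was examined with short pairs over 500 bases from any site: on X the outer part had at most 0.766 of the inner part, which argues against it as the cause of the whole step, but on 2L the ratio was 0.859 in library 2 and 0.936 in library 1, which leaves it open there. It stays open for single windows of X too, since X 1000001 to 2000000 had 0.666 and 0.617 per site but 1.09 and 0.954 for short pairs, and X 11000001 to 12000000 had 0.690 and 0.730 per site but 0.937 and 0.938. Different numbers of copies may account for part of the step on X, as a hypothesis found in the same data.

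The strongest long-range contacts differed in how their pairs were spread. Reads placed at a single pair of fragments are argued against for 2L 17980001 to 18000000 and 2R 11760001 to 11780000, with at most 12.1% of the pairs in a 1 kb by 1 kb cell and neighbouring bin pairs at 21 and 65.2 times the expected value. For the 5 named contacts as a set they stay open: the median of the busiest cell was 52.6% over the 10 values of both libraries, but 46.9% for the lower and 59.8% for the higher library of each contact, where 50% was predicted, and it was 58.3% or more at X 8360001 to 8380000 and 3R 12040001 to 12060000 and 46.9% and 59.8% at X 10500001 to 10520000. Repeat counting of the same molecules as the whole cause is argued against, since 88.3% of the 618 contacts (95% Wilson interval from 85.6%) kept 3 times the expected value in both libraries in 16 base steps, where under 50% was predicted, and the 5 named ones kept 43.1 times or more. This share takes the limit of 3 times alone. The full rule, with at least 10 pairs in each library and the highest value among neighbours, gave 457 contacts in 16 base steps. The 90% set beforehand for excluding it altogether was not reached. For the 72 contacts that fell below 3 times repeat counting stays open, as does the merging of different molecules.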
